A study of Oryza sativa with 8 samples.

How the data were processed

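Root tips of about 2.5 mm were collected from 4-day-old rice seedlings of the wild type and of the Osaim1 mutant (written aim1 here). Seedlings were grown with 500 µM salicylic acid (SA), a plant defence hormone, or without it. Each of the 4 groups had 2 arrays, described by the study as biological repeats, which gave 8 Affymetrix rice genome arrays in all. RNA was extracted with RNeasy columns and labelled with the 3' IVT Express kit. Every array column was assigned to a group from the labels, and 0 columns remained unmapped.

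The deposited values are MAS5 intensity signals on a linear scale, as the authors named the algorithm in their processing notes, where no version is given. The scaling target is not stated. It was inferred from the values, because the mean of each array after leaving out the lowest and highest 2% of probe sets lay between 500.087 and 500.104. No detection calls were used. The table held 57381 probe sets, of which 123 were Affymetrix controls. Of the others, 22436 carried 1 gene symbol, 95 carried several and 34727 carried none. The 17905 distinct genes were looked up in the RefSeq gene table of assembly ASM3414082v1 for their names only, and 2457 had a name other than a locus number or clone. Chromosome positions were not used.

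Background was set for each array as the highest signal of its 27 negative-control probe sets, which ranged from 55.8 to 91.6. Between 37.7% and 45.1% of probe sets per array lay above it. Where both arrays of a group were at or below this level, a fold is given as a lower bound ("at least"), and where both groups were, no fold is given. Where 1 array of a group was at or below it, the deposited signal was kept, which holds for folds of RASI, ADF-6, GSTZ5, GER2, CH16 and ARD1. Folds are ratios of geometric means, while group levels are arithmetic means with their SD.

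Signals were taken to log2 without an offset and fitted with limma 3.58.1 in R 4.3.3, with 4 group means in 1 model, moderated variances and an intensity trend. Control probe sets and probe sets with a mean log2 signal under the 40th percentile (a signal of 18.0) were left out, so 34355 probe sets were tested. The model had 4 residual degrees of freedom and 6.35 prior degrees of freedom. Benjamini-Hochberg correction was applied within each of 6 comparisons, and an adjusted p under 0.05 was taken as passing. The p-values of single probe sets measure spread between these samples, and the number of arrays limits the precision. The tests are two-sided.

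Gene lists were tested with camera from limma at a preset inter-gene correlation of 0.01, on 15768 genes with 1 probe set each (that of highest mean signal). Benjamini-Hochberg correction ran over the lists of a comparison. The list p-values at the preset correlation set members against the other genes and rest on spread across genes, so they do not measure spread between samples. The comparisons, the model, the threshold, most alternatives, the rule for named genes and 22 gene lists were chosen before the data were examined. Those lists had been written for gene descriptions, but the tables given here held symbols only. Only 5 of them reached the minimum of 5 measured members, namely DNA replication and histones, WRKY transcription factors, iron deficiency and metal transport, jasmonate synthesis and TIFY/JAZ, and pathogenesis-related proteins. A further 28 lists on gene symbols were written after the annotation had been seen and before any comparison was computed. Only the 2457 of 17905 genes with a name could enter a list, so measured members are the named part of a family. Family members without a name count among the other genes in the tests. No list call held with an inter-gene correlation estimated from the data, so that adjusted p is given beside each call. That alternative takes its p from the 4 residual degrees of freedom of the model, which by itself makes passing hard. A call lost there therefore does not show that the members are correlated.

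Named genes follow a rule. They are the AIM1 gene, the 12 largest rises and 12 largest falls of each comparison among passing probe sets whose single gene has a name, and up to 4 members of each list with the smallest p. WRKY62, WRKY76, the NPR1 homologue NH1 and PBZ1 are named whatever their values, while WRKY45, PR1a and PR1b were not named in the tables used. The AIM1 gene was taken from background knowledge to be the one annotated MFP. Of its probe sets, only the one matched to that gene alone was used.

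Agreement between comparisons was measured by correlation across probe sets, which are not independent replicates, and by the overlap of calls against the overlap of independent lists. For comparisons that share arrays, the correlation of unchanged groups was obtained from 100 simulations. The pipeline was tested on simulated data in 50 probe sets per fold. For the mutant against the wild type without SA, it recovered 16% of 1.5-fold, 28% of 2-fold, 54% of 4-fold and 70% of 8-fold changes, with 3 false calls among 34355 probe sets. For the difference of SA effects it recovered 2%, 20%, 40% and 58%, with 6 false calls. So few changed probe sets make the Benjamini-Hochberg cutoff stricter than in the real comparisons, so these rates do not give their sensitivity. A shifted list of mitotic genes was called and 0 of the other lists among 26 were, in the comparison of SA with no SA in the wild type with limma. Genes were simulated independently of each other, so this could not test the preset inter-gene correlation.

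Alternatives covered the array scaling (quantile normalization, centring each array on its median), the log offset, the filter, the variance model, array weights, the threshold, a block on the replicate number, fits on fewer arrays, leaving out each array in turn, and other list tests. A floor at the negative controls, median centring of list tests and correlations over arrays not shared were added after the data had been seen. The floor differs between arrays, so a probe set below it in both groups takes the difference of their floors as its change. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.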

Results

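Transcript levels were measured with 8 Affymetrix rice genome arrays on root tips of the wild type and of the aim1 mutant, grown with or without 500 µM SA, with 2 arrays per group. Between 21568 and 25831 probe sets per array lay above the negative controls. The first principal component of the log2 signals held 32.5% of the variance and placed the untreated mutant arrays at 165 and 144, against -75.0 to -15.1 for the other 6. The second held 19.9% and separated untreated from SA-treated wild type. Replicates correlated at r = 0.924 to 0.935 across probe sets, which are not independent replicates. Untreated mutant and untreated wild-type arrays correlated at r = 0.850 to 0.870, and SA-treated mutant and SA-treated wild-type arrays at r = 0.909 to 0.925.

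**Figure D1:**
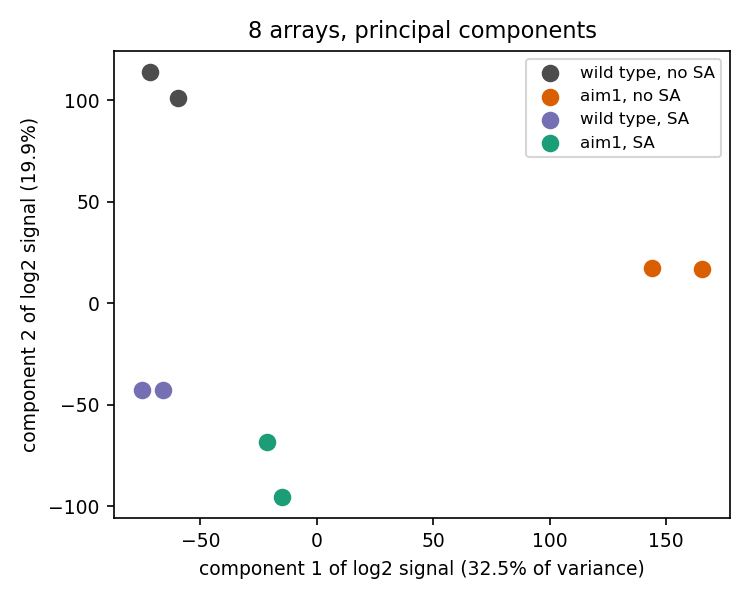
Each point is an array placed on the first (32.5% of the variance) and second (19.9%) principal components of log2 signal, coloured by group with 2 arrays per group. The untreated mutant arrays lie at 165 and 144 on the first component, apart from the other 6 arrays.

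The untreated mutant arrays also differed in their signal distribution. Their upper quartile of signal was 415 and 416, against 317 to 350 on the other arrays, and their median log2 signal over tested probe sets was 7.93 and 7.96 against 7.49 to 7.66. Their 28S ribosomal RNA control signals were 308 and 828, against 811 to 1633 elsewhere. The ratio of the 5' to the 3' actin control was 0.0467 and 0.0965 in the untreated mutant, 0.0633 and 0.0765 in the SA-treated mutant, and 0.103 to 0.129 in the wild type. Centring each array on its median moved the split of every comparison, most in those that use the untreated mutant. The share of higher calls changed by -27.0 percentage points for the genotypes without SA, 25.9 for SA in the mutant and 29.7 for the difference of SA effects. It changed by -12.6 for the genotypes with SA, -12.4 for SA in the wild type and -18.1 for SA-treated mutant against untreated wild type. Both splits are given below.

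MFP (LOC4328997), a multifunctional enzyme of peroxisomal fatty acid beta-oxidation taken here as the AIM1 gene, was low in the mutant with and without SA. Its signal was 14190.2 ± 762 in untreated wild type and 2819 ± 292 in untreated mutant (SD, n = 2 each), 5.04-fold lower (log2 -2.33 ± 0.12 SE, adjusted p = 3.75e-07). With SA it was 29566 ± 895 in the wild type and 3192 ± 575 in the mutant, 9.34-fold lower (adjusted p = 1.17e-06). SA raised MFP 2.08-fold in the wild type (adjusted p = 0.000379), while in the mutant the log2 change was 0.17 (adjusted p = 0.372). The SA effects differed by -0.89 on the log2 scale (adjusted p = 0.00543). Where the probes lie relative to the mutation was not stated in the sources used.

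The untreated mutant was compared with the untreated wild type to describe the genotype effect without added SA. List tests passed towards higher levels for genes of differentiated root tissue, metal handling, aquaporins, glutathione S-transferases and NPR and TGA factors, and towards lower levels for genes of ribosomal proteins, cell division and DNA replication, with part of the members of most lists passing and 0 of these 9 lists called with an estimated correlation (adjusted p = 0.14 to 0.339). NIP2-1 (LOC4330713), the silicon influx transporter, reached 19574 ± 7067 in the mutant against 110.3 ± 6.21 in the wild type (SD, n = 2 each), 172-fold higher (log2 7.42 ± 0.24 SE, adjusted p = 2.03e-08). EXPA1 (LOC4335222), an expansin that loosens cell walls, was at 1051 ± 56.9 against 9207 ± 76.2, 8.77-fold lower (log2 -3.13 ± 0.09 SE, adjusted p = 9.99e-09). In all, 11772 of 34355 probe sets passed, 6244 higher and 5528 lower in the mutant, and 5535 of them changed at least 2-fold, 3667 higher and 1868 lower. With 1 probe set per gene, 7888 of 15768 genes passed, 4153 higher and 3735 lower, and member counts of lists are to be read beside that share.

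Of 40 measured genes of differentiated root tissue (Casparian strip, secondary wall and silicon transport), 19 rose, 1 fell and 20 did not pass (adjusted p = 0.000811, and adjusted p = 0.14 with an estimated correlation). NIP2-1 led them, and the secondary-wall cellulose synthases CESA4 and CESA7 rose 13.4-fold and 17.9-fold. OsCASPL2D1, a Casparian-strip membrane protein-like gene, rose at least 20.7-fold, from below the negative controls to 1229 ± 301. Among 39 genes of iron deficiency and metal transport, 21 rose and 1 fell (adjusted p = 0.000558, and adjusted p = 0.14 with an estimated correlation). They included the metal transporter NRAMP4 (8.77-fold), the nicotianamine synthase NAS3 (8.84-fold) and the yellow stripe-like transporters YSL9 (4.58-fold) and YSL16 (3.48-fold). Metallothioneins rose in 6 of 7 cases (adjusted p = 0.00308, and adjusted p = 0.14 with an estimated correlation), with MT1B 15.5-fold, MT4C 12.9-fold, ERR26 13.6-fold and MT4A 9.12-fold higher. Aquaporins rose in 11 and fell in 1 of 19 cases (adjusted p = 0.00322, and adjusted p = 0.264 with an estimated correlation). PIP2-2 rose 3.40-fold and TIP4-1 13.2-fold, while PIP2-8 was 3.83-fold lower. The untreated mutant arrays that carry these rises are the ones that stood apart on the first component.

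All 5 glutathione S-transferases that had a name and were measured rose (adjusted p = 0.000992, and adjusted p = 0.14 with an estimated correlation). They were led by GSTZ5 at 59.3-fold and GSTU6 at 16.7-fold, with GST1 at 1.91-fold and GSTF2 at 1.82-fold. NPR and TGA factors, which act in SA signalling, rose in 8 of 13 cases and fell in 0 (adjusted p = 0.00677, and adjusted p = 0.14 with an estimated correlation). Examples were TGAL6 (3.90-fold), TGA2.1 (1.85-fold), TGA2.2 (1.80-fold) and TGAL4 (at least 14-fold). NH1, the rice NPR1 homologue, was at 594 ± 43.5 against 471 ± 52.6 (adjusted p = 0.208). Ribosomal protein genes fell in 21 of 25 cases (adjusted p = 2.01e-07, and adjusted p = 0.339 with an estimated correlation), such as rps20 (2.16-fold) and RPS26 (1.95-fold). Mitotic genes fell in 28 and rose in 6 of 43 cases (adjusted p = 0.000764, and adjusted p = 0.221 with an estimated correlation). The B-type cyclins CYCB2-2 and CYCB1-1 were 3.32-fold and 2.13-fold lower and the kinesin KIN14R 2.86-fold lower, while the kinesin KIN12E rose 6.72-fold. DNA replication and histone genes fell in 20 and rose in 2 of 39 cases (adjusted p = 0.000502, and adjusted p = 0.14 with an estimated correlation), among them H2B.11 (1.97-fold) and RPA2A (1.93-fold).

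Other large rises were SIET1 (LOC4331328), at 3660.0 ± 1786 and at least 58.9-fold higher, ZIP1 (LOC4326394), at least 58.9-fold higher, and MEAL1 (LOC4334449), at 29539.8 ± 2218 and 186-fold higher. The esterase gene Pir7b rose 143-fold. The homeobox gene HOX12 rose at least 32.3-fold, BC1 (LOC4333114) at least 36.0-fold, the metallothionein MT2B at least 23.0-fold and the pyruvate decarboxylase PDC1 at least 19.9-fold. The glutaredoxin GRXS3 rose at least 16.4-fold, Agglutinin at least 12.9-fold and DREB2D, a dehydration-responsive factor, at least 9.98-fold. Falls included the arginine decarboxylase ADC2 (8.46-fold), the inhibitor of amylase and subtilisin RASI (8.49-fold), the expansin EXPB18 (7.37-fold), GT3 (7.16-fold), the lipoxygenase LOX1.1 (6.97-fold) and the actin-depolymerising factor ADF-6 (6.87-fold). CSLD1, a cellulose synthase-like gene of root hairs, was at least 10.5-fold lower, BHLH172 at least 6.77-fold and ADF-9 at least 2.40-fold. ILL3 also passed as lower, with only 1 of its mutant arrays above background, so no fold is given. GER8 also passed as lower, with mutant arrays below the negative controls, but turned to 0.26 with the floor (adjusted p = 0.398), and its other probe set had a log2 change of 0.19 (adjusted p = 0.93).

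For the lists chosen beforehand, DNA replication fell in 4 of 6 genes, all MCM helicase subunits, and in 4 adjusted over the list alone (adjusted p = 0.0521 for the list). MCM4 was 1.67-fold and MCM7 1.49-fold lower. Iron and metal transport rose in 5 of 12 genes and in 5 adjusted over the list alone (adjusted p = 0.0521), all of them yellow stripe-like transporters such as YSL12 (2.48-fold) and YSL6 (1.91-fold). The jasmonate list rose in 6 and fell in 2 of 14 genes, with 6 and 2 adjusted over the list alone (adjusted p = 0.29), but rose in 2 and fell in 3 after median centring. JAZ11 rose at least 8.20-fold and JAZ12 5.08-fold, and the falls were GATA17 (1.71-fold) and GATA20 (1.40-fold), GATA factors with a TIFY domain. WRKY factors rose in 3 of 6 cases and in 3 adjusted over the list alone (adjusted p = 0.305), with WRKY51 3.17-fold higher, WRKY71 higher with 1 wild-type array below the negative controls, and WRKY62 passing although all 4 arrays lay below the negative controls. WRKY76 was at 45.7 ± 31.5 against 49.9 ± 13.8 (adjusted p = 0.625). One of 5 pathogenesis-related genes, Rcb4, rose 4.80-fold, and 1 adjusted over the list alone (adjusted p = 0.29). With the floor 3 of the 5 rose, but the floor itself was higher on the untreated mutant arrays (89.5 and 69.4) than on the untreated wild-type arrays (55.8 and 61.1). PBZ1 was at 4080 and 4.49 on the mutant arrays against 1.74 and 3.95 in the wild type (adjusted p = 0.0706).

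Median centring left 3507 probe sets higher and 9976 lower, with the median log2 change of all probe sets at -0.39 against 0.04 as deposited, and quantile normalization 5093 higher and 6628 lower. The list directions called above kept their sign under both. They are relative to the other genes, so centring, which shifts a whole array, could hardly turn them.

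**Figure D2:**
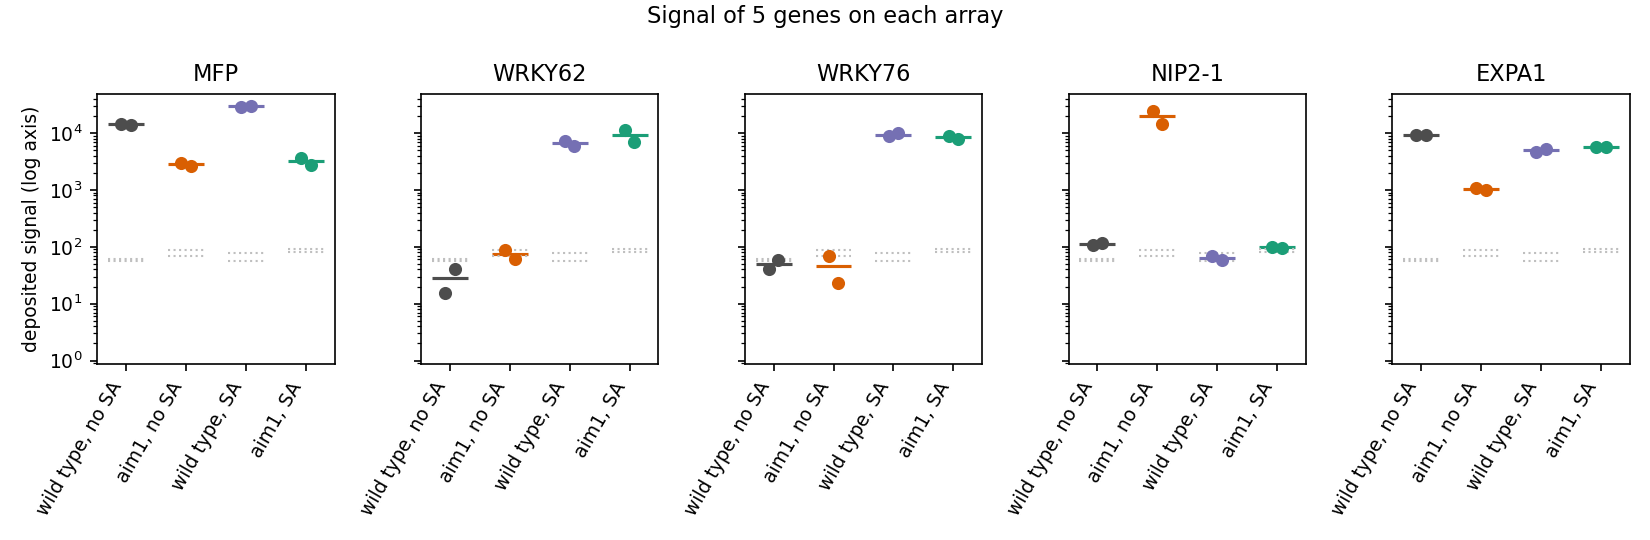
Signal on a log axis of MFP, WRKY62, WRKY76, NIP2-1 and EXPA1 on each array (points), with bars at the mean of the 2 arrays of each group and dotted lines at the highest negative control of each array. NIP2-1 is high only in untreated mutant among the 4 groups (19574 ± 7067, SD, n = 2), and WRKY62 and WRKY76 lie above the negative controls only in the SA-treated groups.

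The SA effect in the wild type came next, with SA-treated against untreated wild-type root tips. WRKY62 (LOC4347070) and WRKY76 (LOC4347069), factors of the SA and defence response, rose from below the negative controls to 6626 ± 983 and 9412 ± 596 (SD, n = 2 each). These rises were at least 113-fold (adjusted p = 6.36e-07) and at least 161-fold (adjusted p = 8.64e-07). Apart from glutathione S-transferases, of which 4 of 5 rose, only a minority of the members of any list by symbol that passed its test changed, as counted below, and 0 of these lists were called with an estimated correlation (adjusted p = 0.164 to 0.721). In all, 2649 probe sets passed, 1426 higher and 1223 lower with SA, and 1221 changed at least 2-fold, 792 higher and 429 lower. Without the intensity trend 805 passed. By gene, 1796 of 15768 passed in the main fit, 928 higher and 868 lower.

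Glutathione S-transferases rose in 4 of 5 cases (adjusted p = 5.3e-07, and adjusted p = 0.164 with an estimated correlation), with GSTU6 16.4-fold, GSTZ5 15.0-fold and GST1 3.43-fold higher. Thioredoxins and glutaredoxins rose in 5 and fell in 1 of 29 cases (adjusted p = 0.0422, and adjusted p = 0.238 with an estimated correlation), among them GRXS5 (3.71-fold), GRXC7 (2.93-fold) and GRXS3 (at least 30.9-fold). Cytokinin genes fell in 7 and rose in 2 of 25 cases (adjusted p = 0.00654, and adjusted p = 0.233 with an estimated correlation), including the response regulators RR2 (4.15-fold) and RR6 (3.22-fold) and the histidine kinase HK4 (3.17-fold). LOGL5, a LOG-like cytokinin-activating gene, rose to 245 ± 43.2 with 1 untreated array below the negative controls. Auxin genes fell in 11 and rose in 2 of 55 cases (adjusted p = 0.0355, and adjusted p = 0.238 with an estimated correlation), with ARF7 1.83-fold lower and GH3.2 2.53-fold higher. Aquaporins fell in 4 of 19 cases (adjusted p = 0.0355, and adjusted p = 0.369 with an estimated correlation), such as PIP2-2 (2.18-fold) and PIP1-3 (at least 4.73-fold). In the ribosomal protein list, 1 of 25 genes fell, RPS10-1 by a factor of 1.34 (adjusted p = 0.0355, and adjusted p = 0.721 with an estimated correlation). Median centring ended the calls of aquaporins (adjusted p = 0.0601, range over alternatives 0.00651 to 0.369), auxin (0.0601, 0.00642 to 0.238) and thioredoxins (0.0761, 0.00173 to 0.238). Leaving out the filter ended those of aquaporins (0.179) and thioredoxins (0.114), and quantile normalization ended that of ribosomal proteins (0.469, 0.000212 to 0.721).

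The WRKY list, chosen beforehand, rose in 2 of 6 genes and in 2 adjusted over the list alone (adjusted p = 0.0218, and adjusted p = 0.221 with an estimated correlation). Of 13 NPR and TGA factors 3 rose and 10 did not pass. The list test did not pass at the preset correlation (adjusted p = 0.155) but did with fry, another list test (adjusted p = 0.0205). Those that rose were NH3 (5.08-fold), NH2 (2.22-fold) and NPR4 (2.28-fold), while NH1 was at 315 ± 22.8 against 471 ± 52.6 (adjusted p = 0.0997). Among 5 pathogenesis-related genes, PBZ1 of the PR10 family rose at least 23.6-fold to 1408 ± 424 (adjusted p = 0.0314), and CH16 was 10.7-fold lower, with 2 up and 2 down adjusted over the list alone (adjusted p = 0.946). The list's median log2 change was -1.44 and its mean 0.58. The median rests on signals below background, as it was -0.11 with log2(signal + 32). With the floor it was 0.20, a value set by the floors, which differ between arrays, and not a measured change. Jasmonate genes fell in 3 and rose in 1 of 14 cases, with 3 and 1 adjusted over the list alone (adjusted p = 0.193), for example JAZ4 (1.90-fold) and JAZ1 (1.42-fold) lower and JAZ6 higher. They fell in 1 and rose in 0 after quantile normalization, and 3 and 0 after median centring. One of 12 iron and metal transport genes fell, YSL15 by a factor of 4.42, and 1 adjusted over the list alone (adjusted p = 0.946, median log2 change 0.13 and mean -0.03). None of 6 DNA replication genes passed with limma, 0 adjusted over the list alone and 0 at an unadjusted p under 0.05 (adjusted p = 0.946).

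The largest other rises were the beta-glucosidase BGLU31 (92.7-fold), RH2 (37.4-fold), OPR10 of the oxophytodienoate reductase family (26.5-fold) and HAK17 of the potassium transporter family (20.2-fold). The argonaute AGO18 rose to 604 ± 140.4 with 1 untreated array below the negative controls. Falls included the expansin EXPB18 (20.4-fold), the germin-like gene GER2 (18.9-fold), and a gene named peroxidase (at least 11.3-fold). PLP2 was at least 5.65-fold lower, GLU6 at least 5.37-fold, OsCASPL1D1 at least 3.05-fold, mdr17 at least 1.91-fold and IAA20 (LOC4340245) at least 1.14-fold. GER1 and AT5 also passed as lower, with only 1 untreated array each above background, and their direction turned under a floor at the negative controls.

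Median centring gave 1195 higher and 1688 lower. The count fell to 1536 without replicate 2 of the untreated wild type, 1335 without replicate 1 of the SA-treated wild type and 1306 without its replicate 2.

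The SA effect in the mutant was taken from SA-treated against untreated mutant root tips. List tests passed towards lower levels with SA for differentiated root tissue, metal transport, metallothioneins, aquaporins, auxin and cytokinin, and towards higher levels for ribosomal proteins, mitosis and DNA replication, with members passing in part as counted below and 0 of these 9 lists called with an estimated correlation (adjusted p = 0.104 to 0.411). NIP2-1 was at 97.8 ± 0.61 with SA against 19574 ± 7067 without (SD, n = 2 each), 194-fold lower (log2 -7.60 ± 0.24 SE, adjusted p = 4.89e-08). WRKY76 and WRKY62 rose at least 106-fold (adjusted p = 7.09e-07) and at least 112-fold (adjusted p = 1.43e-06), to 8367 ± 711 and 9092 ± 2960.4. In all, 8698 probe sets passed, 4272 higher and 4426 lower with SA, and 3495 changed at least 2-fold, 1224 higher and 2271 lower. Without the intensity trend 5125 passed. By gene, 5950 of 15768 passed in the main fit, 2959 higher and 2991 lower, and member counts of lists are to be read beside that share.

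Differentiated root tissue fell in 21 and rose in 1 of 40 genes (adjusted p = 5.66e-06, and adjusted p = 0.104 with an estimated correlation), with CESA7 15.2-fold, CESA4 14.1-fold and IRX9L 2.68-fold lower. Iron and metal genes by symbol fell in 17 and rose in 1 of 39 cases (adjusted p = 0.000486, and adjusted p = 0.171 with an estimated correlation), such as NAS3 (8.05-fold), YSL9 (5.44-fold) and NRAMP4 (5.32-fold). Nicotianamine synthases NAS1 and NAS2 were 72.1-fold and 53.0-fold lower, with wide spread in the treated arrays (623 ± 667 and 610.1 ± 611). Metallothioneins fell in 6 of 7 cases (adjusted p = 0.000655, and adjusted p = 0.146 with an estimated correlation), among them MT4C (30.0-fold), MT1B (22.6-fold) and MT2B (at least 15.5-fold). Aquaporins fell in 12 and rose in 2 of 19 cases (adjusted p = 0.000556, and adjusted p = 0.188 with an estimated correlation), for instance PIP1-3 (45.6-fold), PIP2-5 (9.73-fold) and PIP2-2 (4.44-fold). Auxin genes fell in 27 and rose in 5 of 55 cases (adjusted p = 0.00147, and adjusted p = 0.146 with an estimated correlation), with ARF1 4.73-fold and GH3.2 3.39-fold lower. Cytokinin genes fell in 10 of 25 cases (adjusted p = 0.0196, and adjusted p = 0.171 with an estimated correlation), with RR9 2.94-fold and HK5 2.59-fold lower.

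Ribosomal protein genes rose in 17 and fell in 1 of 25 cases (adjusted p = 5.66e-06, and adjusted p = 0.411 with an estimated correlation), among them rps20 (1.77-fold) and RPS26 (1.68-fold). Mitotic genes rose in 24 and fell in 5 of 43 cases (adjusted p = 0.0113, and adjusted p = 0.381 with an estimated correlation), with KIN14R 2.63-fold and CYCB1-1 1.87-fold higher and KIN12E 5.90-fold lower. DNA replication and histone genes rose in 11 and fell in 1 of 39 cases (adjusted p = 0.0113, and adjusted p = 0.171 with an estimated correlation), including H2B.11 (1.72-fold). CMT3, a DNA methyltransferase that the list also holds, was 1.67-fold higher. These lists moved with the same arrays whose actin ratios and 28S signals are given above.

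Of the lists chosen beforehand, iron and metal transport fell in 6 of 12 genes and in 6 adjusted over the list alone (adjusted p = 0.0197, and adjusted p = 0.511 with an estimated correlation), led by YSL15 at 15.2-fold. That call was lost without the filter on dim probe sets (adjusted p = 0.111, range over alternatives 0.00248 to 0.511). WRKY factors rose in 2 and fell in 1 of 6 cases, with 2 and 1 adjusted over the list alone (adjusted p = 0.227), the fall being WRKY51 (1.85-fold). They rose in 2 and fell in 0 after quantile normalization, 3 and 0 after median centring, and 2 and 2 with the floor. Jasmonate genes fell in 6 and rose in 2 of 14 cases, with 6 and 2 adjusted over the list alone (adjusted p = 0.129), such as JAZ7 (2.34-fold) and JAZ1 (2.03-fold). Of 6 DNA replication genes, MCM4 rose 1.54-fold, and 1 did adjusted over the list alone (adjusted p = 0.403). Of 5 pathogenesis-related genes, CH16 was 9.12-fold lower, and 1 fell adjusted over the list alone (adjusted p = 0.403), with PBZ1 at 3128 ± 128 against 2042 ± 2882 (adjusted p = 0.174).

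Further rises were RH2 (58.1-fold), HAK17 (20.4-fold), the late embryogenesis gene LEA19 (16.6-fold), RASI (12.3-fold), the nucleoredoxins OsNrx1-1 (10.4-fold) and OsNrx1-2 (6.81-fold), NH3 (7.32-fold), AGO18 (6.22-fold) and the dehydrin RAB16D (at least 2.16-fold). CRYD passed with only 1 treated array above background. NPR and TGA factors fell in 6 and rose in 2 of 13 cases without a passing list test at the preset correlation (adjusted p = 0.319), but fell in 2 and rose in 3 after median centring. Among them NH1 was 1.65-fold lower (adjusted p = 0.0155). Further falls were MEAL1 (201-fold), SIET1 (at least 39.7-fold), TIP1 (at least 29.3-fold), RAA1 (at least 15.3-fold), BGLU34 (at least 10.0-fold), the heat shock gene HSP23.2 (at least 5.08-fold) and BCL1 (at least 2.32-fold). Median centring gave 7768 higher and 2585 lower, with the median of all probe sets at 0.26 against -0.03 as deposited.

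**Figure D3:**
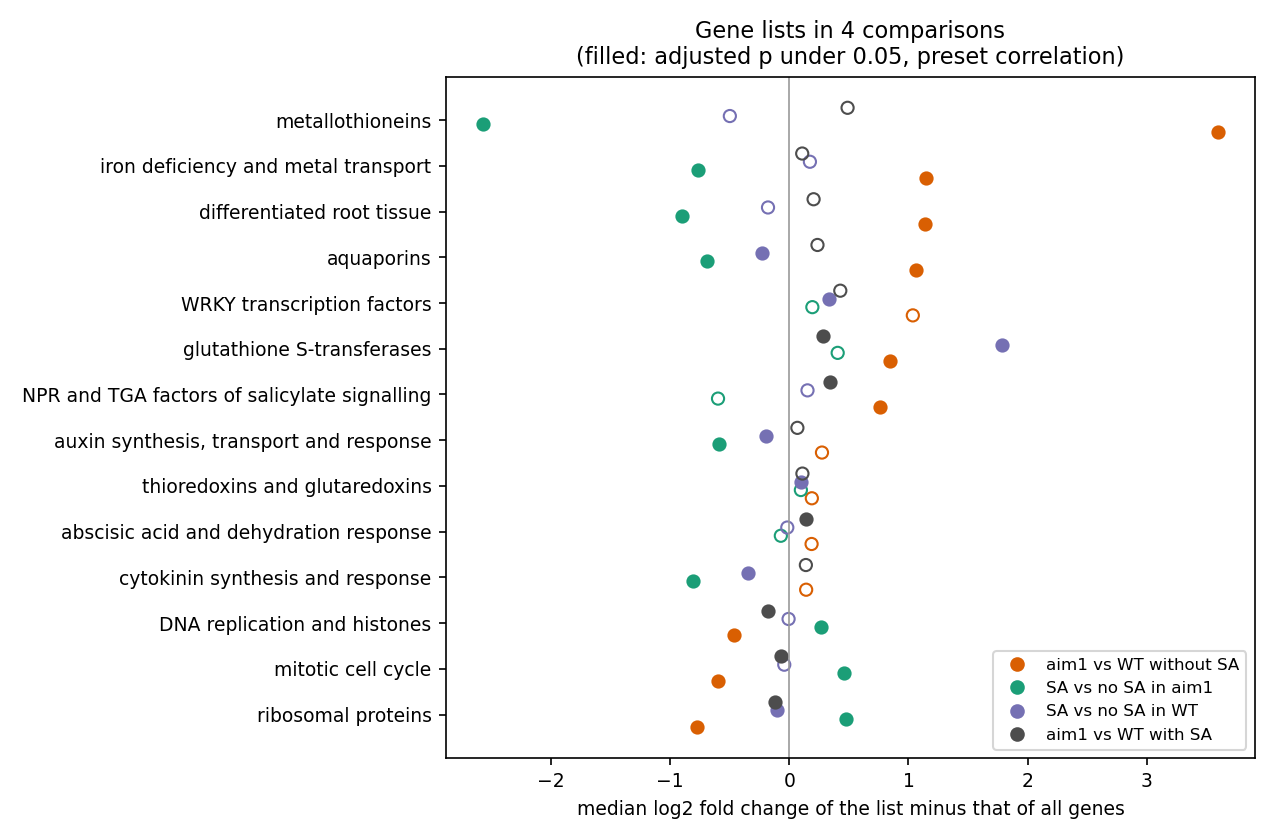
Median log2 fold change of 14 gene lists minus that of all genes, in the mutant against the wild type without and with SA, and with against without SA in each genotype. Filled points passed the list test at an adjusted p under 0.05 with the preset correlation and none passed with an estimated one; the differentiated tissue, metal and metallothionein lists lie to the right in the untreated mutant and to the left for SA in the mutant.

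The difference between the SA effects of the genotypes (mutant minus wild type) was tested directly. List tests passed towards a lower SA effect in the mutant for differentiated tissue, metal, metallothionein, aquaporin and glutathione S-transferase genes, and towards a higher one for ribosomal, mitotic and DNA replication genes, although in several lists most members did not pass and 0 of these 8 lists were called with an estimated correlation (adjusted p = 0.181 to 0.338). NIP2-1 was high in untreated mutant and low elsewhere, with 68.8 and 58.0 on the SA-treated wild-type arrays, of which 1 lay above the negative controls. Its SA effects differed by -6.79 ± 0.34 (log2, SE, adjusted p = 3.8e-06), and by -7.02 with signals raised to the floor. EXPA1 differed by 3.35 ± 0.12 (adjusted p = 3.02e-07), since SA lowered it 1.86-fold in the wild type and raised it 5.47-fold in the mutant. In all, 5871 probe sets passed, 2886 with a higher and 2985 with a lower SA effect in the mutant, and 2973 differed at least 2-fold, 995 higher and 1978 lower. Without the intensity trend 1681 passed, 668 higher and 1013 lower. By gene, 4136 of 15768 passed in the main fit, 2106 higher and 2030 lower, and member counts of lists are to be read beside that share.

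Differentiated root tissue had a lower SA effect in 15 of 40 genes and a higher one in 0 (adjusted p = 0.00047, and adjusted p = 0.181 with an estimated correlation), with CESA4 at -4.02, CESA7 at -3.29 and LAC10 at -4.28 on the log2 scale. Iron and metal genes by symbol were lower in 14 and higher in 1 of 39 cases (adjusted p = 0.000304, and adjusted p = 0.181 with an estimated correlation), such as NAS3 (-3.33) and NRAMP4 (-3.25). Metallothioneins were lower in 4 of 7 cases (adjusted p = 0.00454, and adjusted p = 0.181 with an estimated correlation), among them MT1B (-3.48) and MT2C (-3.64). Aquaporins were lower in 8 and higher in 1 of 19 cases (adjusted p = 0.0138, and adjusted p = 0.336 with an estimated correlation), as for PIP2-5 (-3.45). Glutathione S-transferases were lower in 4 of 5 cases (adjusted p = 0.0012, and adjusted p = 0.181 with an estimated correlation), with GSTZ5 at -3.55 and GSTU6 at -3.02. Ribosomal protein genes had a higher SA effect in 17 of 25 cases (adjusted p = 1.94e-07, and adjusted p = 0.338 with an estimated correlation), with rps20 at 0.97. Mitotic genes were higher in 15 and lower in 4 of 43 cases (adjusted p = 0.00338, and adjusted p = 0.304 with an estimated correlation), with KIN12E at -2.77. DNA replication and histone genes were higher in 8 and lower in 1 of 39 cases (adjusted p = 0.0176, and adjusted p = 0.208 with an estimated correlation), with H2B.11 at 0.85.

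WRKY62 and WRKY76 rose in both genotypes from untreated levels below the negative controls, so no size is given for the difference of their SA effects (adjusted p = 0.216 and 0.909). For PBZ1, below the controls on 3 of 4 untreated arrays, none is given either (adjusted p = 0.387). NH1 differed by -0.15 (adjusted p = 0.767). The iron list chosen beforehand was lower in 4 of 12 genes and in 5 adjusted over the list alone (adjusted p = 0.0279, and adjusted p = 0.576 with an estimated correlation), for example YSL9 (-2.01) and YSL16 (-1.73), and lost its call without the filter (adjusted p = 0.0926, range over alternatives 0.00445 to 0.576). Jasmonate genes were higher in 2 and lower in 2 of 14 cases, with 2 and 4 adjusted over the list alone (adjusted p = 0.593). In the DNA replication, pathogenesis-related and WRKY lists chosen beforehand, 0 members passed with limma and 0 adjusted over the list alone. After median centring 3 DNA replication genes passed as higher, and with the floor 1 pathogenesis-related and 1 WRKY gene passed as lower. At an unadjusted p under 0.05 there was 1 of 6 DNA replication genes (adjusted p = 0.593), 1 of 5 pathogenesis-related genes (adjusted p = 0.632, median log2 difference 0.23 and mean -0.86, with a median of -0.84 with the floor and -0.46 with log2(signal + 32)) and 0 of 6 WRKY genes (adjusted p = 0.593).

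Among the other named genes with every array above the negative controls, the SA effect was lower in the mutant for MEAL1 (-7.58) and higher for EXPB18 (3.36), ADC2 (3.33), LOX1.1 (2.99), LEA19 (2.62) and GT3 (2.55). The remaining genes had arrays below the controls, so their values are given with signals raised to that floor and not ranked. Lower SA effects in the mutant were then found for SIET1 (-5.51), TIP1 (-5.24), BC1 (LOC4333114) (-4.98), ZIP1 (LOC4326394) (-4.35), GRXS3 (-3.12), HSP23.2 (-2.55), PIN5 (-2.18) and OsCASPL1U2 (-1.71), and higher ones for CSLD1 (3.42), GLU6 (2.91), ADF-6 (2.70), RASI (2.66), ADF-9 (2.31) and RR1 (1.97). BGLU9 (-0.11, adjusted p = 0.937) and the vacuolar iron transporter VIT1.2 (-0.35, adjusted p = 0.692) passed as deposited and no longer did with the floor. Median centring gave 6194 higher and 1664 lower, with the median of all probe sets at 0.31 against -0.06 as deposited.

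With SA, the genotypes were compared to describe what of the mutant's difference remains in treated root tips. Among named genes above background in both groups, MFP had the largest fall in fold, and Pir7b rose 20.6-fold, from 636 ± 107 in the wild type to 12987 ± 523 in the mutant (SD, n = 2 each, log2 4.36 ± 0.22 SE, adjusted p = 6.78e-06). AOX1, an alternative oxidase, rose 5.65-fold to 9369.9 ± 2259 (adjusted p = 2.99e-05). Far fewer genes passed than without SA: 1029 probe sets, 686 higher and 343 lower in the mutant, of which 472 changed at least 2-fold, 385 higher and 87 lower. By gene, 694 of 15768 passed, 495 higher and 199 lower, and member counts of lists are to be read beside that share.

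Abscisic acid and dehydration genes rose in 4 and fell in 0 of 68 cases (adjusted p = 0.0208, and adjusted p = 0.301 with an estimated correlation), namely ABA8OX1 (2.08-fold), OsPP2C15 (1.57-fold), OsPP2C27 (2.98-fold) and LEA19 (1.47-fold). Glutathione S-transferases rose in 2 of 5 cases, GSTZ5 5.06-fold and GSTU6 2.06-fold (adjusted p = 0.00118, and adjusted p = 0.28 with an estimated correlation). NPR and TGA factors rose in 2 of 13 cases (adjusted p = 0.0439, and adjusted p = 0.321 with an estimated correlation), NH2 1.42-fold and TGAL4 with both groups below the negative controls. Among DNA replication and histone genes 0 of 39 passed with limma and 9 had an unadjusted p under 0.05, while the list as a whole was lower (adjusted p = 0.000899, and adjusted p = 0.28 with an estimated correlation). PCNA, the sliding clamp of DNA polymerase, was at 4709.8 ± 226 against 6161 ± 301 (adjusted p = 0.0871). Mitotic genes fell in 2 of 43 cases, CDKB2-1 by a factor of 1.42 and KIN14F by 2.00 (adjusted p = 0.0479, and adjusted p = 0.403 with an estimated correlation). The ribosomal protein list was lower with 0 of 25 genes passing with limma and 2 at an unadjusted p under 0.05 (adjusted p = 0.0439, and adjusted p = 0.559 with an estimated correlation). Quantile normalization ended the calls of mitotic genes (adjusted p = 0.0558, range over alternatives 0.0285 to 0.403), NPR and TGA factors (0.0558, 0.0211 to 0.321) and ribosomal proteins (0.0745, 0.00029 to 0.676).

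In the lists chosen beforehand, DNA replication was lower with 0 of 6 genes passing with limma, 0 adjusted over the list alone and 2 at an unadjusted p under 0.05 (adjusted p = 0.0236, and adjusted p = 0.222 with an estimated correlation). Rcb4 rose 2.18-fold among 5 pathogenesis-related genes, with 1 adjusted over the list alone (adjusted p = 0.126) and 0 after median centring or quantile normalization, and JAZ12 rose 4.63-fold among 14 jasmonate genes, with 1 adjusted over the list alone (adjusted p = 0.344). For WRKY factors 0 of 6 passed with limma and 1 rose adjusted over the list alone, with 3 at an unadjusted p under 0.05 (adjusted p = 0.344). WRKY62 was at 9092 ± 2960.4 against 6626 ± 983 (adjusted p = 0.673) and WRKY76 at 8367 ± 711 against 9412 ± 596 (adjusted p = 0.889). Iron and metal transport had 0 of 12 passing with limma, 0 adjusted over the list alone and 3 at an unadjusted p under 0.05 (adjusted p = 0.344), with a median log2 change of 0.03 (-0.03 after median centring) and a mean of -0.05. PBZ1 was at 3128 ± 128 against 1408 ± 424 (adjusted p = 0.858) and NH1 at 362 ± 69.3 against 315 ± 22.8 (adjusted p = 0.698).

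Other rises were the peroxiredoxin R1C-Prx (11.5-fold), the trehalose-phosphate phosphatase TPP1 (8.95-fold), the calmodulin-like CML31 (7.76-fold), APR1 (7.53-fold), EL2 (6.05-fold) and PDC1 (at least 6.75-fold). OPR5 rose 7.83-fold, although its other probe set had a log2 change of -0.40 (adjusted p = 0.92). Falls were the small heat shock gene HSP18.8 (2.59-fold), the aquaporin PIP2-5 (2.27-fold), the brassinosteroid factor BZR1 (2.22-fold), ABCG37 (1.97-fold), ADF-11 (1.86-fold), URH2 (1.86-fold), the D-type cyclin CYCD6-1 (1.85-fold) and OsCASPL1U2 (at least 1.22-fold). AT5, GER1 and BGLU9 passed with both groups below the negative controls and BHLH172 with 1 wild-type array above, so no fold is given for these 4, and BGLU9 turned direction with the floor.

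Median centring gave 600 higher and 510 lower. The count moved to 2002 with a floor at the negative controls, 78 without the intensity trend, 268 without replicate 1 of the SA-treated mutant, and 469 and 392 without replicate 1 or 2 of the SA-treated wild type.

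The SA-treated mutant was also set against the untreated wild type, to describe how far these groups lay apart. Genotype and SA differ together here, so this comparison cannot tell their effects apart. The beta-glucosidase BGLU31 rose 237-fold, from 91.7 ± 47.9 to 20210.2 ± 83.6 (SD, n = 2 each, log2 7.89 ± 0.26 SE, adjusted p = 2.49e-08), and GSTU6 rose 33.8-fold to 32054 ± 3385 (adjusted p = 4.06e-09). WRKY62 and WRKY76 rose at least 152-fold and at least 143-fold. In all, 5568 probe sets passed, 2800 higher and 2768 lower, and 2348 changed at least 2-fold, 1589 higher and 759 lower. Without the intensity trend 2316 passed. By gene, 3718 of 15768 passed in the main fit, 1865 higher and 1853 lower.

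Glutathione S-transferases rose in 4 of 5 cases (adjusted p = 5.59e-06, and adjusted p = 0.216 with an estimated correlation), with GSTZ5 76.0-fold and GST1 4.12-fold higher. Thioredoxins and glutaredoxins rose in 10 and fell in 1 of 29 cases (adjusted p = 0.0158, and adjusted p = 0.226 with an estimated correlation), such as GRXS5 (4.90-fold) and GRXS3 (at least 58.2-fold). NPR and TGA factors rose in 5 of 13 cases (adjusted p = 0.0333, and adjusted p = 0.248 with an estimated correlation), among them NH3 (6.68-fold), NPR4 (4.65-fold) and NH2 (3.16-fold), with NH1 at 362 ± 69.3 against 471 ± 52.6 (adjusted p = 0.209). DNA replication and histone genes fell in 6 of 39 cases (adjusted p = 0.0158, and adjusted p = 0.226 with an estimated correlation), such as PCNA (1.47-fold). Ribosomal protein genes fell in 4 of 25 cases (adjusted p = 0.00214, and adjusted p = 0.669 with an estimated correlation), such as RPS7 (1.28-fold). Quantile normalization ended the ribosomal call (adjusted p = 0.0597, range over alternatives 7.3e-06 to 0.669), and leaving out the filter ended that of NPR and TGA factors (adjusted p = 0.0525, 0.00207 to 0.248).

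Of the lists chosen beforehand, WRKY factors rose in 2 of 6 genes and in 3 adjusted over the list alone (adjusted p = 0.00997, and adjusted p = 0.174 with an estimated correlation). DNA replication fell in 2 of 6 genes, MCM2 (1.33-fold) and MCM3 (1.29-fold), and in 2 adjusted over the list alone (adjusted p = 0.0792). Iron and metal transport rose in 2 of 12 genes, YSL12 (1.43-fold) and YSL16 (1.35-fold), and in 3 adjusted over the list alone (adjusted p = 0.589, median log2 change 0.06 and mean -0.08), with 0 and a median of -0.08 after median centring. Jasmonate genes rose in 2 and fell in 4 of 14 cases, with 3 and 4 adjusted over the list alone (adjusted p = 0.589), for example JAZ12 (3.71-fold) higher and JAZ4 (1.84-fold) lower. Pathogenesis-related genes rose in 2 and fell in 1 of 5 cases, with 2 and 1 adjusted over the list alone (adjusted p = 0.589). PBZ1 rose at least 53.6-fold (adjusted p = 0.00919) and Rcb4 3.99-fold, while CH16 was 9.60-fold lower.

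Other rises were RH2 (50.1-fold), Pir7b (47.7-fold), OPR10 (42.6-fold), HAK17 (31.8-fold) and PDC1 (at least 7.75-fold). Falls were EXPB18 (14.6-fold), GER2 (13.6-fold), the gene named peroxidase (at least 8.72-fold), BHLH172 (at least 6.17-fold), CIPK29 (at least 3.81-fold), BGLU34 (at least 2.13-fold), IAA14 (at least 1.94-fold) and EXPB9 (at least 1.77-fold). ARD1 was 11.2-fold lower, with a log2 change of 0.46 (adjusted p = 0.29) at its other probe set. BGLU9 and OsCASPL1U2 passed as lower but turned direction under a floor at the negative controls. Median centring gave 2236 higher and 4713 lower, with the median of all probe sets at -0.15. The count was 3527 without replicate 2 of the untreated wild type and 3217 without replicate 1 of the SA-treated mutant.

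Across probe sets, the size of effects shared by replicates, as a root mean square log2 difference, was 1.07 for the genotypes without SA, 0.41 with SA, 0.61 for SA in the wild type and 0.92 for SA in the mutant. The genotype effects without and with SA correlated at r = 0.23 (rho = 0.25), and at 0.0947 without the filter and 0.382 with log2(signal + 32). There were 585 probe sets higher in both against 125 in independent lists, and 258 lower in both against 55.2, with 26 and 15 in opposite directions against 62.3 and 110. The SA effects in the 2 genotypes correlated at r = 0.18 (rho = 0.0813), and at 0.0703 without the filter and 0.263 with log2(signal + 32), with 579 raised in both against 177 and 541 lowered in both against 158, and 206 and 205 in opposite directions against 184 and 152. The genotype effect without SA and the SA effect in the mutant share the untreated mutant arrays and correlated at r = -0.62 (rho = -0.61), against -0.50 in simulations of unchanged groups. Their covariance was -0.936 against -0.242 simulated. Because of the shared arrays, independent lists are no value for unchanged groups here. Of the genes involved, 3153 probe sets higher in the mutant were lowered by SA against 804 in independent lists, and 3300 lower in the mutant were raised by SA against 687.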

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

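All technical explanations weighed here, and their tests, were chosen only after the results had been seen, while the test of the difference between the genotypes' SA effects was planned. Results are listed here because that test passed for them, on 2 arrays per group.

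The SA effect differed between the genotypes for 5871 probe sets with limma, and for 1681 without the intensity trend. At the level of gene lists the adjusted p of this difference was 0.0279 for the iron and metal transport list chosen beforehand (0.576 with an estimated correlation). Among lists by symbol the test passed towards a lower SA effect in the mutant for iron and metal genes (adjusted p = 0.000304), differentiated root tissue (0.00047), glutathione S-transferases (0.0012), metallothioneins (0.00454) and aquaporins (0.0138). It passed towards a higher one for ribosomal proteins (1.94e-07), mitotic genes (0.00338) and DNA replication and histones (0.0176). With an estimated correlation these lists had an adjusted p of 0.181, 0.181, 0.181, 0.181, 0.336, 0.338, 0.304 and 0.208 in the order given. For MFP the SA effects differed by -0.89 on the log2 scale.

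Values as deposited follow on the log2 scale, and only those of EXPB18, EXPA1, ADC2, LOX1.1, LEA19, GT3 and MEAL1 have every array above the negative controls. The named genes with a higher SA effect in the mutant were ADF-9 (5.51), GLU6 (5.24), CSLD1 (3.46), EXPB18 (3.36), EXPA1 (3.35), ADC2 (3.33), RASI (3.03), LOX1.1 (2.99), ADF-6 (2.89), RR1 (2.64), LEA19 (2.62) and GT3 (2.55). Those with a lower one were SIET1 (-11.33), TIP1 (-8.03), MEAL1 (-7.58), PIN5 (-6.89), BC1 (LOC4333114) (-6.88), NIP2-1 (-6.79), HSP23.2 (-6.73), ZIP1 (LOC4326394) (-6.68), VIT1.2 (-6.60), BGLU9 (-5.71), OsCASPL1U2 (-5.65) and GRXS3 (-5.40). For all but the 7 genes above, the size rests in part on signals below the negative controls. With signals raised to that floor SIET1 fell in size to -5.51, TIP1 to -5.24, PIN5 to -2.18, HSP23.2 to -2.55, OsCASPL1U2 to -1.71 and ADF-9 to 2.31. BGLU9 (-0.11, adjusted p = 0.937) and VIT1.2 (-0.35, adjusted p = 0.692) no longer passed.

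The first pattern is that the genotype difference was far larger without SA (11772 probe sets) than with SA (1029). Array scaling as the whole cause is argued against. The ratio of calls was 11.44 as deposited, 12.2 after quantile normalization and 12.15 after median centring. With the floor and with log2(signal + 32), which do not rescale arrays, it was 6.56 and 9.73. Degraded RNA in the untreated mutant arrays stays open: for 0 of 4 control transcripts was the 5' to 3' ratio lowest in both of those arrays, with cyclophilin (0.469 and 0.557) and ubiquitin (1.17 and 1.40) within the range of the others, but 1 of them had the lowest actin ratio (0.0467) and 28S signal (308) of all 8, and the other the highest GAPDH ratio (0.253, against 0.0834 in the first and 0.0555 to 0.0969 elsewhere). A larger share of differentiated tissue in the untreated mutant tips may contribute and stays open. The list of differentiated root tissue lay 1.14 above all genes (log2) while mitotic genes fell. With an estimated correlation its test did not pass (adjusted p = 0.14), but on 4 residual degrees of freedom it could hardly do so. That list is named for Casparian strip, secondary wall and silicon transport, so it does not stand for all differentiated cells. CSLD1, a gene of root hairs, went the other way and was lower in the untreated mutant. A change of expression within cells, a biological alternative given by the genotypes, was not tested against such a larger share and would look alike in pooled tips.

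The second pattern is that SA in the mutant moved genes against the genotype difference, as for NIP2-1 (24571 and 14577 in the untreated mutant) and MEAL1 (31108 and 27971), high on both of its arrays. By construction, the difference of SA effects equals the genotype difference with SA minus that without SA. The second pattern, the first and the flagged results are therefore not independent of each other. Noise of the shared untreated mutant arrays as the whole cause is argued against, because pairings that share no array gave a mean r of -0.339 (-0.36 to -0.311 over 8 pairings). No label names a batch or date, so separate handling of the untreated mutant arrays is not known, and no value here decides it. Of the calls between genotypes with SA, 81.9% recurred without SA in the same direction, against 17.5% for independent lists, but only 7.16% of the calls without SA recurred with SA. A return of mutant transcript levels towards the wild type through SA is the biological alternative in the design and stays open as a hypothesis.

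The third pattern is that genes higher in the untreated mutant overlapped those raised by SA in the wild type, with 990 probe sets in both against 259 in independent lists and 596 lower in both against 197, and 236 against 222 and 106 against 229 in opposite directions. Both comparisons use the untreated wild-type arrays, so independent lists are no value for unchanged groups. Noise of the shared untreated wild-type arrays as the whole cause is argued against, because pairings that share no array gave a mean r of 0.11 (0.0873 to 0.132). With shared arrays r was 0.383, against 0.499 in 100 simulations of unchanged groups, so that r is no evidence of overlap, while the covariance was 0.487 against 0.241. No biological explanation was tested.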

How the results depend on the processing

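The floor at the negative controls, median centring of list tests, and all alternatives for lists by symbol were chosen only after the data had been seen. Alternatives not mentioned left the counts of passing probe sets within 1.5 times the reported ones. Values are given for the mutant against the wild type without SA (A) and with SA (B), for SA in the wild type (C) and in the mutant (D), for the difference of SA effects (E) and for SA-treated mutant against untreated wild type (F).

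Without the intensity trend the counts were 78 (B), 805 (C), 5125 (D), 1681 (E) and 2316 (F). A minimum of 2-fold left 5535 (A), 472 (B), 1221 (C), 3495 (D), 2973 (E) and 2348 (F), by its construction. B rose to 1789 at an adjusted p under 0.1, by construction, and to 2002 with the floor. With a replicate block the counts were 11907, 1239, 2844, 8910, 6127 and 5773 in the same order, but replicate numbers do not pair the groups, as deviations from group means correlated at -0.0087 to 0.0146. The correlation of the genotype effects without and with SA was 0.0947 without the filter and 0.382 with log2(signal + 32), that of the SA effects 0.0703 and 0.263, and that of the genotype effect without SA against SA in the mutant -0.681 with log2(signal + 32). The cause was not tested.

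Leaving out 1 array at a time, with the lone array taken to vary like the other groups, gave 9273 to 11504 (A), 268 to 1128 (B), 1306 to 2795 (C), 6446 to 8511 (D), 3976 to 5283 (E) and 3217 to 5825 (F). Counts moved over 1.5 times for B without aim1 SA replicate 1 (268), wild-type SA replicate 1 (469) or 2 (392), for C without wild-type control replicate 2 (1536), wild-type SA replicate 1 (1335) or 2 (1306), and for F without wild-type control replicate 2 (3527) or aim1 SA replicate 1 (3217). The 3 correlations ranged over 0.181 to 0.217, 0.147 to 0.178 and -0.692 to -0.542. Of 610 passing values of named genes, 231 no longer passed without the trend, 201 at a minimum of 2-fold, 31 after median centring, 26 after quantile normalization, 17 without the filter and 34 to 87 without single arrays.

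Of 30 tests of the lists chosen beforehand 5 passed, against 0 with an estimated correlation, 12 with fry, 13 with fry and a replicate block, 3 without the filter, 8 after median centring, and 2 (without aim1 SA replicate 2) to 11 (without aim1 control replicate 2) over single arrays left out. Of 156 tests of lists by symbol 45 passed, against 0 with an estimated correlation, 73 with fry (41 of the 45 calls among them), 78 with fry and a replicate block (40), and 37 to 46 over single arrays. Among the calls that fry added in A were DNA replication, iron and WRKY of the lists chosen beforehand. By symbol they included abscisic acid, auxin, jasmonate, cytokinin, ethylene and heat shock genes, all towards higher levels. Fry ended ribosomal in B (0.311), C (0.278) and F (0.0786) and mitotic in B (0.15), and with a replicate block also abscisic acid in B (0.0574). Testing all probe sets ended thioredoxins in C (0.078). Called directions held in all of these, while 42 of the 45 calls passed after median centring and 40 after quantile normalization. A replicate block ended the calls of mitotic genes, NPR and TGA factors (both adjusted p = 0.0518) and ribosomal proteins (0.0547) in B.

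Single arrays ended these list calls, with the adjusted p. Without wild-type control replicate 1: mitotic in B (0.0529) and aquaporins (0.0633), auxin (0.0754) and thioredoxins (0.0633) in C. Without its replicate 2: mitotic in B (0.0532), ribosomal (0.618) and WRKY (0.0994 and 0.0862 by symbol) in C. Without wild-type SA replicate 1: mitotic (0.0575) and ribosomal (0.119) in B and ribosomal in C (0.0504). Without its replicate 2: DNA replication chosen beforehand (0.056), abscisic acid (0.103), mitotic (0.103), NPR and TGA (0.112) and ribosomal (0.0846) in B, and in C aquaporins and auxin (both 0.105), ribosomal and thioredoxins (both 0.127) and WRKY (0.128 and 0.111). Without aim1 SA replicate 1: mitotic in B (0.139) and DNA replication in F (0.0539). Without its replicate 2: DNA replication chosen beforehand (0.124), abscisic acid (0.0891), NPR and TGA (0.166) and ribosomal (0.676) in B, iron chosen beforehand in D (0.0718) and E (0.097), aquaporins in E (0.0549), and NPR and TGA (0.103) and ribosomal (0.0942) in F.

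Direction turned for CAT-B in A after median centring (log2 -0.43, adjusted p = 0.00373), by the shift of all probe sets. Under the floor it turned for WRKY76 (0.43, adjusted p = 0.0311) and GER8 (0.26) in A, BGLU9 (0.37) in B, GER1 (0.19) and AT5 (0.20) in C, and BGLU9 (0.57) and OsCASPL1U2 (0.32) in F, all with arrays below the negative controls, whose level differs between arrays and sets these values. With fry and a replicate block it turned for the pathogenesis-related list chosen beforehand in F (signed -log10 p of -2.01) and for enzymes that remove reactive oxygen in D (-1.79), and the cause was not tested.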

Other observations

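No tests in this part were chosen beforehand except the list tests by symbol, which were written before any comparison was computed. Several pathways close to the mutated gene or to SA changed in members without a passing list test at the preset correlation. In the untreated mutant 7888 of all 15768 genes passed, so many passing members there do not mark a list. In fatty acid beta-oxidation and peroxisomes, 6 genes rose and 3 fell of 12 in the untreated mutant (adjusted p = 0.782), but 1 and 3 after median centring. Phenylpropanoid genes, with 17 measured, rose in 8 and fell in 4 cases (adjusted p = 0.299), with 6 and 6 after median centring, and in the mutant SA raised 1 and lowered 8 (adjusted p = 0.173), with 5 and 5 after median centring. Of 4 diterpenoid phytoalexin genes 2 rose in the untreated mutant, too few for a list test, and 2 also rose after median centring.

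Hormone genes other than those of SA had no passing list test at the preset correlation in the untreated mutant. With fry, another list test, their lists passed towards higher levels. The adjusted p was then 0.00502 for abscisic acid, 0.00141 for auxin, 0.035 for jasmonate, 0.0207 for cytokinin and 0.00611 for ethylene. Fry was run without centring the arrays. The share of passing members in these lists lay near or below that of all genes (7888 of 15768). Abscisic acid and dehydration genes rose in 21 and fell in 10 of 68 cases (adjusted p = 0.334), with 12 and 21 after median centring. Auxin genes rose in 21 and fell in 9 of 55 (adjusted p = 0.201), with 13 and 16 after median centring, and jasmonate genes by symbol rose in 11 and fell in 6 of 33 (adjusted p = 0.46), with 5 and 10. Cytokinin genes rose in 7 and fell in 5 of 25 (adjusted p = 0.791), with 5 and 9 after median centring. Ethylene genes rose in 5 and fell in 1 of 17 (adjusted p = 0.299), with 3 and 1.

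Cell wall and redox genes went both ways, as all genes did in the untreated mutant (4153 higher and 3735 lower of 15768). Expansins and xyloglucan hydrolases rose in 10 and fell in 6 of 26 cases in the untreated mutant (adjusted p = 0.782), with 9 and 10 after median centring. Enzymes that remove reactive oxygen rose in 6 and fell in 5 of 21 (adjusted p = 0.791), with 5 and 11 after median centring and 12 and 4 after quantile normalization. Thioredoxins and glutaredoxins rose in 9 and fell in 3 of 29 (adjusted p = 0.437), with 5 and 11 after median centring. Heat shock genes rose in 5 and fell in 2 of 19 (adjusted p = 0.475, and 0.00691 with fry), with 3 and 6, and phosphate starvation genes rose in 4 and fell in 1 of 14 (adjusted p = 0.544), with 2 and 2. Chitinases and other pathogenesis-related genes fell in 4 and rose in 1 of 11 cases with SA in the wild type (adjusted p = 0.126), the same numbers as after median centring.

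Some transcripts differed more than 16-fold between the arrays of a group with at least 1 of them above the negative controls. There were 200 such probe sets in untreated wild type, 83 in untreated mutant, 187 in SA-treated wild type and 34 in SA-treated mutant. PBZ1 was among them, at 4080 and 4.49 in the untreated mutant, while it was at 1.74 and 3.95 in untreated wild type, 1108 and 1708 in SA-treated wild type and 3219 and 3038 in SA-treated mutant.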
